A study of Arabidopsis thaliana with 2 samples.

How the data were processed

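Stem RNA of Arabidopsis thaliana was measured on the Affymetrix ATH1 GeneChip, an array on which each transcript is read by a set of short oligonucleotide probes (a probe set). There were 2 samples, 1 of wild-type plants and 1 of plants overexpressing AtC3H14 (35S::AtC3H14), with 1 array each. Per the labels, both were Columbia (Col-0) plants grown on soil to 30 days of age with 16 h of light and 8 h of dark at 23 °C, the stem was taken from its base up to the third internode, and biotinylated cRNA was made from 10 ug of total RNA extracted with Trizol.

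The deposited values are probe-set intensity values on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version is not given in the sources used here. The 2% trimmed mean of the deposited signals was 500.04 on each array. With the averages of the arrays equal, a shift of all transcripts in one direction cannot be seen in these values. The values used here came without detection calls, and no array scan was analysed here.

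The table held 22810 probe sets. The 64 control probe sets were set apart, and 22746 were analysed. Low signals were limited by a floor, the 40th percentile of all non-control signals of both arrays, which was 104.0. All 27 control probe sets for bacterial transcripts outside the spiked hybridization controls lay below it, with a highest signal of 62.4. A probe set below the floor on both arrays was given no ratio. A probe set below it on 1 array was given only a bound, computed against the floor and written as "at least N-fold". Ratios are 35S::AtC3H14 over wild type. With 1 array per group no test, standard error or p-value was computed, no array could be left out in turn, and probe sets were described by a fixed size of 2-fold. The number of arrays limits the precision. The one spread that could be had was that between probe sets of the same gene on the same arrays, a pooled SD of 0.35 in log2 ratio over 117 probe sets of 58 genes. It leaves out all variation between plants, extractions and hybridizations.

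Probe sets were named through the platform annotation, matched to the TAIR10.1 gene table. Of the 22746 probe sets, 13513 named 1 gene, 503 named several and 8730 were not listed and are unnamed here. Of those naming 1 gene, 1551 carried a symbol other than the locus code, and 29 had no match in the gene table. No gene was named from a probe set with several genes. The build behind the array design is not given in the sources used here, so no coordinates are printed.

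Before the data were examined, 28 gene lists with 415 entries, the size rule, the floor, the alternatives and the rule for named genes were fixed. That rule names AtC3H14. It adds the 10 highest and 10 lowest ratios among probe sets naming 1 gene with a symbol, above the floor on both arrays and with a mean log2 signal at or above the median of all probe sets. It adds the 5 largest bounds in each direction among those naming 1 gene with a symbol. From each list it takes up to 4 measured members with the largest change, and any member of a list of technical kind. A list was described by the median log2 ratio of its measured members, with members at a bound entered at that bound, if it had at least 3. The percentile of that median among 10000 random lists of the same size, each gene drawn from the 200 nearest in mean signal, describes these 2 arrays and is no test.

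Only 64 of the 415 entries had a probe set naming that gene alone, and 49 of these were measured on at least 1 array. Of the 415 loci, 410 carried the listed name in the gene table and 5 carried no name besides the locus code (PGX2, PGX3, UGT75C1, A9 and TIP41-like). Several readings of the rules were settled after values had been seen. These were keeping the 5 loci just named, reading a symbol as one other than the locus code, matching a locus where the Entrez number had no match, and the spreads against which alternatives were judged. Those spreads were the SD between probe sets for genes and the SD of random lists for list medians. Without UGT75C1, PGX3 and TIP41-like, the flavonoid, pectin and reference lists would have 2 measured members each and no median. Families of genes sharing the letters of their symbol were scanned after seeing the data. In that scan the GH3 and GH9 genes, which are unrelated, were first pooled by the letters GH and were separated after the pooled result had been seen. For the 25S ribosomal RNA, the bounds for RNA degradation and for carry-over of RNA without poly(A) tails were made stricter after the values had been seen. By those bounds both explanations were left open. For the expansins and xyloglucan endotransglucosylase/hydrolases, a test of signal-dependent bias by loess, written beforehand, was dropped after its value had been seen, because the random lists are already matched on signal.

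The alternatives were centring each array on its median, quantile normalization, loess of the log2 ratio on mean signal with a span of 0.4, no floor, a floor at the 60th percentile (308.5), a pseudocount of 104.0 in place of the floor, a 3-fold size, leaving out probe sets with an _s_at or _x_at suffix, the brightest probe set per gene, and the inclusion of probe sets naming several genes. Scaling to the 18 hybridization-control probe sets was added after seeing the data.

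The calculation was tested on simulated arrays of 22746 probe sets, with a noise SD of 0.2 in log2 per array. Simulated differences were placed only in probe sets with a mean signal at least 4 times the floor. The 2-fold size found 7.35% of 68 probe sets simulated at 1.5-fold, 92.1% of 63 at 2.5-fold and 98.6% of 69 at 4-fold, and 0.038% of 13193 unchanged ones. The shares found do not cover differences in dimmer genes, some of which are named below. Of 200 random lists of 6 genes, 6.5% lay outside the central 95%. The noise level was chosen, not measured, so these shares say nothing about the error between plants. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.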

Results

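Transcript levels were compared between 1 stem sample of wild-type Arabidopsis and 1 of plants expressing AtC3H14 from the 35S promoter, a strong viral promoter active in most plant tissues. AtC3H14 (AT1G66810) encodes a CCCH zinc finger protein, and the series names it as a target of MYB46, a transcription factor of secondary wall formation. The median signal was 180 on the wild-type array and 194 on the 35S::AtC3H14 array. Signals reached the floor of 104.0 for 13424 probe sets (59.0%) on the wild-type array and for 13871 (61.0%) on the other. There were no replicates, so no difference given here was set against variation between plants. The labelled age, growth conditions and stem part were the same for both samples. Unlabelled differences in plant, stage or harvest cannot be separated from genotype.

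The first comparison was of AtC3H14 itself, which checks the labels. Its probe set had a signal of 244 in wild type and 8655 in the overexpressor, 35.5-fold higher, a log2 ratio of 5.15. The direction was that of the genotype label. The probe set does not tell transcripts of the transgene from those of the native gene.

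The second comparison asked which other transcripts differed in the overexpressor. The highest named transcripts included an expansin, a xyloglucan-modifying enzyme and an endoglucanase, and the lowest included a sugar transporter, an anthocyanin enzyme and a vascular signalling peptide. EXPA15 (AT2G03090), an expansin, a protein that loosens cell walls, was 8.64-fold higher, from 265 to 2293. XTH16 (AT3G23730), a xyloglucan endotransglucosylase/hydrolase that cuts and rejoins the xyloglucan chains of the wall, was 5.79-fold higher. SWEET11 (AT3G48740), a sucrose exporter that acts in phloem loading, was 13.1-fold lower, from 5346 to 407. DFR (AT5G42800), dihydroflavonol reductase of anthocyanin synthesis, was 6.76-fold lower, from 2993 to 443.

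Of 12826 probe sets at or above the floor on both arrays, 579 were at least 2-fold higher and 720 at least 2-fold lower in the overexpressor, together 10.1%. A further 184 were higher and 116 lower by a bound of at least 2-fold. At 4-fold or more, 55 were higher and 74 lower, and at 8-fold or more, 7 and 16. The log2 ratios had a median of 0.04 and an SD of 0.64. Higher probe sets made up 44.6% of those past 2-fold. This split rests on the scaling of the arrays. When the arrays were scaled to the hybridization controls, a choice made after seeing the data, 207 were higher and 2143 lower, so that higher ones made up 8.81%, and the median log2 ratio moved to -0.46. With no floor 3428 were higher and 2409 lower, or 58.7% higher. Fold differences in the text are therefore relative to the average of each array. Of the changed probe sets, 278 higher and 355 lower ones are unnamed here.

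**Figure D1:**
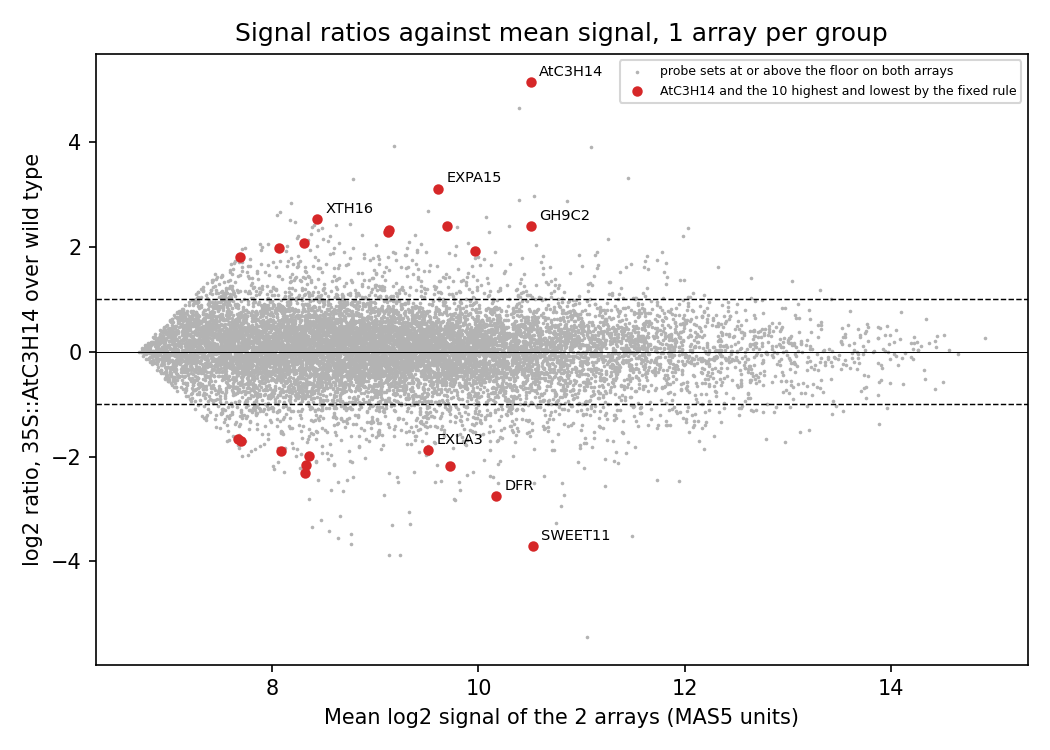
Log2 ratio of 35S::AtC3H14 over wild type against the mean log2 signal of the 2 arrays, in MAS5 units, for the 12826 probe sets at or above the floor on both arrays (grey). Red points are AtC3H14 and the 10 highest and 10 lowest named genes, and dashed lines mark 2-fold. AtC3H14 stands at 5.15 and SWEET11 at -3.71.

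Among the 10 highest named genes, DRT100 was 5.30-fold higher and GH9C2, an endoglucanase of glycosyl hydrolase family 9, was 5.28-fold higher. WES1 (also GH3.5), an enzyme that conjugates auxin to amino acids, was 5.01-fold higher, and ATPMEPCRD, a pectin methylesterase, 4.87-fold. TUB1, a beta-tubulin, was 4.23-fold higher. TBL28, of a family that includes wall polysaccharide acetyltransferases, was 3.92-fold higher, LCR68, a small cysteine-rich protein, 3.78-fold, and scpl46, a serine carboxypeptidase-like protein, 3.51-fold. Genes below the floor in wild type had only bounds. The 5 largest were at least 9.45-fold for XTH18, 6.92-fold for the pectin methylesterase ATPMEPCRB, 6.26-fold for the subtilase SBT1.3, 5.33-fold for GLC and 4.59-fold for XTH19.

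Among the 10 lowest, TBL26 was 4.97-fold lower, ATL8, a RING-type ubiquitin ligase, 4.55-fold, and AGO7, an Argonaute protein of trans-acting small RNA production, 4.48-fold. UBC16 was 3.99-fold lower. CLE44, a precursor of the peptide that restrains xylem differentiation and maintains the vascular cambium, was 3.72-fold lower, from 524 to 141. EXLA3, an expansin-like protein, was 3.69-fold lower, SWEET16, a sugar transporter of the vacuole membrane, 3.28-fold, and GRX480, a glutaredoxin, 3.17-fold. The largest lower bounds, for genes below the floor in the overexpressor, were at least 8.75-fold for JRG21, 6.52-fold for ADPG1, 5.92-fold for the peptide gene RALFL31, 5.90-fold for PYK10, a beta-glucosidase of ER bodies, and 5.35-fold for scpl30. With the floor at the 60th percentile, which turns ratios of dim genes into smaller bounds, 2-fold was no longer shown for TBL28 (a log2 ratio of 0.78), scpl46 (0.33), GLC (0.84), XTH19 (0.63), CLE44 (-0.76), SWEET16 (-0.28), GRX480 (-0.24), RALFL31 (-0.998), PYK10 (-0.99) and scpl30 (-0.85).

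The xyloglucan endotransglucosylase/hydrolase and expansin lists had medians high among their random lists. The measured member brightest in wild type was lower in the overexpressor in each list. XTH27 went from 6471 to 2647 and EXLA1 from 7495 to 2974. Of 6 measured xyloglucan endotransglucosylase/hydrolases, 4 were at least 2-fold higher (XTH18, XTH16, XTH19 and XTH32, the last 3.23-fold), XTH33 had a ratio of 1.35, and XTH27 was 2.44-fold lower. Their median log2 ratio was 1.94, at the 100th percentile of 10000 random lists, and it stayed at or above the 98.88th percentile under every alternative, although the median itself was 0.31 with the pseudocount. The value of 1.94 lies between the log2 ratio of XTH32 (1.69) and the bound of XTH19 (2.20). XTH18 and XTH19 are close relatives whose probe sets can share signal. Of 11 measured expansins, 3 were at least 2-fold higher, EXPA15, EXLA2 (2.79-fold) and EXPA4 (2.02-fold), and 2 were lower, EXLA3 and EXLA1 (2.52-fold). XTH27, XTH33, EXPA4 and the expansins without a 2-fold ratio fall outside the rule for named genes and are named after their values were seen. With the hybridization-control scaling EXLA2 had a log2 ratio of 0.96 and EXPA4 of 0.49, so that EXPA15 was the expansin still shown past 2-fold higher, and with the pseudocount EXPA4 had 0.95. Of the other 6, EXPA9 and EXPB3 lay under 2-fold, and EXPA8, EXPA20, EXPB1 and EXLB1 had bounds under 2-fold, which leave their size open. The expansin median was 0.54, which is the bound of EXPB1, at the 99.49th percentile. With no floor it was at the 92.65th and with the pseudocount, where the median was 0.17, at the 82.32nd, so its place outside the central 95% depends on how low signals are handled.

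Of the 3 measured genes of flavonoid and anthocyanin synthesis, 2 were at least 2-fold lower, DFR and the anthocyanin glycosyltransferase UF3GT (2.61-fold), and UGT75C1 was 1.53-fold below wild type, with a log2 ratio of -1.14 in the hybridization-control scaling. The median of -1.38 lay at the 0.21st percentile. This list of 12 entries is known here by 3 genes only. Among auxin-related genes 4 were measured. WES1 was the 1 member at least 2-fold higher, IAA18 was 1.61-fold below wild type (a log2 ratio of -1.21 with the hybridization-control scaling), and IAA29 and GH3.3 had bounds of 1.62-fold and 1.22-fold above it. The median of 0.49, midway between the bounds of IAA29 and GH3.3, lay at the 95.36th percentile, inside the central 95%. With no floor and with the pseudocount, each over 8 genes, it lay at the 99.92nd and the 99.71st. The genes added there, IAA20, IAA30, GH3.1 and SAUR10, lay below the floor on both arrays, so these places rest in part on very low signals.

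The 4 measured genes of xylan synthesis, IRX10, IRX10-L, IRX15 and IRX15-L, all lay under 2-fold, with a median of -0.04 at the 38.92nd percentile, and IRX15 differed most, 1.37-fold below wild type. In lignin synthesis HCT was 1.38-fold and CCR2 1.71-fold below wild type, both under 2-fold, and with the hybridization-control scaling CCR2 passed 2-fold lower, at a log2 ratio of -1.30. COB, which acts in cellulose deposition in primary walls, had a log2 ratio of 0.31, and -0.21 when scaled to the hybridization controls. Of 3 pectin genes, ADPG1, a polygalacturonase of pod and anther dehiscence, was at least 6.52-fold lower, PGX3 had a bound of 1.44-fold above wild type and PME35 a ratio of 1.05. The pectin median of 0.06, at the 52.59th percentile, and the mean of -0.70 differed in sign. The median became -0.70 with no floor and -0.46 with the hybridization-control scaling. Of the gibberellin receptors, GID1C was 2.21-fold lower (a log2 ratio of -0.78 with the pseudocount and -0.11 with the floor at the 60th percentile), GID1A had a log2 ratio of -0.16 and GID1B of -0.02, with a list median of -0.16 at the 31.47th percentile.

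The lists of secondary wall cellulose synthesis, secondary wall transcription factors, xylem vessel and fiber differentiation, fasciclin-like arabinogalactan proteins, brassinosteroid genes, aquaporins, tandem CCCH zinc finger proteins, cell division, phloem and senescence had no probe set naming 1 member alone. The floral list had A9 alone, which lay below the floor on both arrays. The response of these lists was not analysed here.

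Genes of other tissues and of handling were read beside these lists. The photosynthetic list had a median of 0.04, at the 61.25th percentile, with LHCB4.1 1.25-fold below wild type and PRK and RCA at ratios of 1.07 and 1.03. PHV, a vascular patterning gene, was 2.01-fold lower, just past 2-fold, and had a log2 ratio of -0.87 with the pseudocount. WSD1, a wax ester synthase of the epidermis, was at least 4.48-fold higher. THI2.1, a defence thionin, had a ratio of 1.61. ZAT10, which responds to touch and wounding among other stresses, was 3.05-fold higher, and COR15A, a cold-response gene, 3.11-fold higher. With the floor at the 60th percentile WSD1 had a log2 ratio of 0.59 and COR15A of 0.94. Each of these 5 genes was the sole measured member of its list. GI, the one measured clock gene, was 1.15-fold below wild type. The 3 reference genes SAND, UBC21 and TIP41-like had log2 ratios of -0.00355, -0.05 and 0.34, with a median at the 48.26th percentile.

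**Figure D2:**
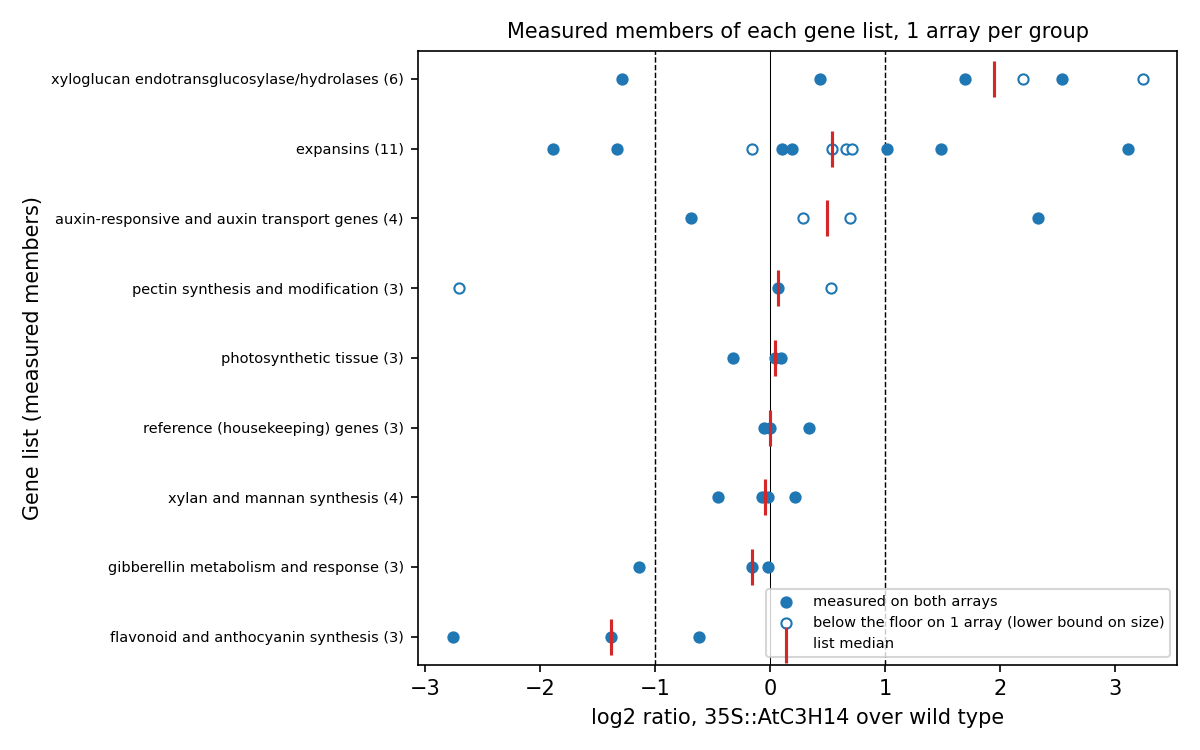
Log2 ratio of 35S::AtC3H14 over wild type for the measured members of the 9 lists with at least 3, the number measured in brackets. Filled points were above the floor on both arrays, open points are bounds from 1 array, red bars are list medians, and dashed lines mark 2-fold. The xyloglucan endotransglucosylase/hydrolase median stands at 1.94 and the flavonoid median at -1.38, and with the hybridization-control scaling these were 1.56 and -1.90 while the photosynthetic median of 0.04 turned to -0.48.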

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

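All tests of the 25S ribosomal RNA were chosen after the result was seen. Control probe sets outside the comparisons above showed signals above their level in wild type. The probe set for 25S ribosomal RNA had a signal of 361 in wild type and 4209 in the overexpressor, 11.6-fold higher. The probe set for the 3' end of GAPDH in the second control series had a signal of 5438 in wild type and 11622 in the overexpressor, 2.14-fold higher, but with the hybridization-control scaling its log2 ratio of 1.10 became 0.57, under 2-fold. The other GAPDH control probe sets had log2 ratios from 0.62 to 0.83, all under 2-fold, and from 0.10 to 0.31 with that scaling.

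For 25S, array scaling alone would move the hybridization controls as far. Their mean log2 shift was 0.52, with an SD of 0.17 over probe sets that share transcripts and a highest shift of 0.81, against 3.54 for 25S. RNA degradation in the overexpressor sample would raise the ratio of 3' to 5' signal. The median log2 change over 6 ratios was -0.078, with 5 of them below 0 and GAPDH of the second control series at 0.29. This median lay within the SD of 0.19, which leaves degradation open. General carry-over of RNA without poly(A) tails could raise plastid and mitochondrial transcripts together. Plastid-encoded transcripts lay at the 99.8th percentile and mitochondrion-encoded ones at the 0.53rd, or at the 40.69th with the floor at the 60th percentile. The median log2 ratio was 0.25 over 68 plastid genes, the highest at 1.21. It was -0.46 over 9 mitochondrial genes, the highest at 0.36. Carry-over that raised these transcripts as far as 25S would place them near 3.54, so these values argue against it. A smaller or uneven carry-over stays open. More ribosomal RNA in the stem could only mean a larger share of the 10 ug of total RNA that both samples started from. The 5S ribosomal RNA, with a log2 ratio of 0.40, could not decide this, since it was below the floor in wild type.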

How the results depend on the processing

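The scaling to the hybridization controls was chosen after seeing the data; the other alternatives were planned. No ratio or median past 2-fold as deposited changed sign. Most alternatives shift such ratios little or shrink them, so this could hardly have come out otherwise. Medians under 2-fold did change sign. Pectin went from 0.06 to -0.70 with no floor, and the photosynthetic list from 0.04 to -0.48 with the hybridization-control scaling. Median centring, quantile normalization and loess moved no list median and no AtC3H14 ratio past its spread and no count by over 1.5 times. The brightest probe set and probe sets naming several genes were tried on list medians only, and leaving out _s_at and _x_at probe sets on counts only, with the same outcome. With no floor, 3428 probe sets were higher and 2409 lower, and the medians were 1.29 for xyloglucan endotransglucosylase/hydrolases, -0.70 for pectin and 1.57 for auxin. With the floor at the 60th percentile, 261 were higher and 429 lower, and the xyloglucan endotransglucosylase/hydrolase median was 1.44; pectin, auxin and gibberellin genes were then too few for a median. With the pseudocount, which by construction shrinks ratios of low signals, AtC3H14 had a log2 ratio of 4.65, expansins 0.17 and xyloglucan endotransglucosylase/hydrolases 0.31. At 3-fold, 162 were higher and 182 lower. The hybridization-control scaling lowers by 0.52, by construction, each log2 ratio of a gene that stays above the floor on both arrays, and by less where the floor then sets a bound. It gave 207 higher and 2143 lower, 4.63 for AtC3H14, and medians of 0.30 for expansins, 1.56 for xyloglucan endotransglucosylase/hydrolases, -0.46 for pectin, 0.17 for auxin, -0.57 for xylan, -0.68 for gibberellin, -1.90 for flavonoid, -0.48 for photosynthetic and -0.53 for reference genes. The 18 control probe sets were all higher on the overexpressor array, by 1.44-fold on average. They read the spiked transcripts bioB, bioC, bioD and cre several times each, so they are not 18 separate controls. Whether the shift came from less stem RNA on that array or more control RNA was not tested. For 87 genes named or measured in a list, 446 of 596 values stayed within the spread and 150 moved: 70 with the hybridization-control scaling, all downward, 36 with the pseudocount, 30 of 74 with the floor at the 60th percentile and 14 with no floor. Of those past 2-fold, 15 of 53 were under it with the floor at the 60th percentile, 5 of 54 with the pseudocount, 4 with the hybridization-control scaling and 1, PHV, with quantile normalization. Of 33 under 2-fold, 3 passed it downward with the hybridization-control scaling (CCR2, IAA18 and UGT75C1), 5 passed it with no floor, 4 of them upward, and 2 passed it upward with the pseudocount. Signals near the floor limit what can be read: 8277 probe sets lay below it on both arrays. No paired analysis was possible because each group has 1 array.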

Other observations

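The gene families described here were scanned after seeing the data, and the test of handling was chosen after the result was seen; the test without XTH18 and XTH19 was written before. Of 35 families sharing the letters of their symbol, 6 had a median at or above the 99th percentile of matched random lists and 1 at or below the 1st. If all genes varied independently, 0.7 families would be placed outside. Genes of a family need not vary independently, so the count is no test against chance. XTH27, which was 2.44-fold lower, carries the symbol EXGT-A3 in the gene table and was left out of the scanned family. The other 5 measured xyloglucan endotransglucosylase/hydrolases and the EXPA expansins were among the 6, and their lists had already been seen to be high. The others were the GH9 endoglucanases, the CSLC glycosyltransferases, which make the xyloglucan backbone, the beta-tubulins and a group of bHLH transcription factors. Of 7 GH9 genes, 6 were above wild type, with a median log2 ratio of 0.70 and GH9C2 and GH9B8 at 2.40 and 1.34. All 5 CSLC genes had ratios above 1, with a median of 0.74, as did all 5 beta-tubulins, with a median of 0.78 and TUB1 at 2.08. With the hybridization-control scaling these medians were 0.43, 0.22 and 0.25, against -0.46 for all measured probe sets. The GH9 value is then over 6 genes, since GH9C3, one of the lower members, fell below the rescaled floor on both arrays, and GH9B13, CSLC04 and TUB6 then lay below wild type. The bHLH median of 0.75 lay at the 99.08th percentile over 5 genes, 3 of them above 0. It is the bound of BHLH101, and the EXPA median of 0.71 is the bound of EXPA20. With loess the bHLH group lay at the 98.71st percentile and EXPA at the 98.8th, both under the 99th. With the floor at the 60th percentile, the bHLH median was at the 83.19th percentile, that of GH9 (0.40 over 6 genes) at the 98.71st and that of CSLC (3 genes) at the 98.29th, all under the 99th, and EXPA had 2 genes and no median, while the beta-tubulins stayed at the 99.64th. GH9B8 was then at 0.58, at 0.82 with the hybridization-control scaling and at 0.98 with the pseudocount.

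The UGT glycosyltransferases had a median of -0.37 at the 0.19th percentile, with 14 of 19 genes below 0 and 1 past 2-fold. With the floor at the 60th percentile the median was -0.29 over 10 genes, at the 2.14th percentile. All 8 ATG8 and ATG3 autophagy genes measured were below 0, with a median of -0.44 at the 2.34th percentile. Of 8 SWEET sugar transporters, SWEET11, SWEET16 and SWEET2 were more than 2-fold lower and SWEET14 and SWEET4 more than 2-fold higher. SWEET14 had a log2 ratio of 0.26 with the floor at the 60th percentile, and SWEET4 of 0.80 with the hybridization-control scaling and 0.78 with the pseudocount. The plastid-encoded transcripts had a median of 0.25 over 68 genes, 45 of them above 0, and -0.27 with the hybridization-control scaling.

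Several loci without a symbol changed more than most named genes, and are given here after their values were seen. AT5G03350 was 15.1-fold higher, from 149 to 2251. AT1G78780 and AT3G26450 were 14.7-fold and 14.6-fold lower, and AT1G64370 was 11.4-fold lower, from 9741 to 852.

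The expansins and xyloglucan endotransglucosylase/hydrolases, pooled, had a median log2 ratio of 0.66 over 17 genes, at the 99.99th percentile. That median is the bound of EXPA8, and it was 0.23 at the 98.8th percentile with the pseudocount and 0.41 with the hybridization-control scaling. The random lists are matched on signal and the pattern was picked by its place among them, so its percentile is no separate test of a signal-dependent bias. With loess the pooled median was 0.57, that of the xyloglucan endotransglucosylase/hydrolases 1.90 and that of the expansins 0.45. As deposited these were 0.66, 1.94 and 0.54, so a trend with signal over the whole arrays accounts for a small part of them. Without XTH18 and XTH19 the pooled median was 0.54 over 15 genes, at the 99.84th percentile, so this pair of close relatives does not set it. Taking 2 high members from 17 can move a median only little, so this check could hardly have come out otherwise. The xyloglucan endotransglucosylase/hydrolase list alone was not tested without the pair. A handling or cold difference between the 2 harvests stays open: the 2 measured members of the touch and cold lists, ZAT10 and COR15A, were both at least 2-fold higher, and several genes of this wall family are known to respond to touch. With 1 array per genotype, a hypothesis that AtC3H14 overexpression raises these transcripts cannot be told apart from a difference in plant, stage or handling.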
